A study of Mus musculus with 30 samples.

How the data were processed

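Neural retina of Abca4-/-Rdh8-/- mice was measured by stranded poly(A) RNA sequencing in 30 libraries of 10 groups, 3 per group. Per the labels, the single-drug experiment and the mixture experiment were performed and analysed separately, so each was fitted by itself. The requested depth was 50 M read pairs. The authors trimmed reads with Trimmomatic, named Bowtie2 and TopHat2 for alignment, and quantified transcripts of GRCm38.p3 with eXpress. They named edgeR and limma for normalization and testing. Versions are not given in the sources used here.

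The deposited count tables hold expected counts (eXpress effective counts) for 102906 transcripts, which are fractional and not normalized. The deposited normalized tables hold FPKM values that the authors scaled by TMM, for protein-coding transcripts past an expression filter. The tables of changed transcripts hold log2 fold changes of each group against the light group, computed by the authors. The same tables give an adjusted p-value of an F test over all groups, also by the authors. The deposited FPKM tables made directly by eXpress were not analysed here.

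Expected counts were summed over the transcripts of each of 42439 gene identifiers and rounded. Genes were filtered with filterByExpr at its default settings, libraries were scaled by TMM, and all groups of an experiment were fitted together with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3. The test was two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The SE of a log2 fold change is its absolute value over the square root of the F statistic. The light effects of the experiments were compared in a fit of all libraries, as the difference between light and no light in each. There were 17 comparisons. Total gene counts per library set the precision of single genes, and counting error is only part of the spread between libraries.

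The genes named in the text were chosen by a rule fixed before the data were examined. For light and for each mixture these were the 10 called genes with the largest rise and the 10 with the largest fall. For each single drug they were the 5 of each. Such genes had a mean log2 CPM of at least 1 and no overlap between the groups' libraries. Members of 37 gene lists, written down with the rule, add to these: the 4 members of a described list with the smallest adjusted p for light in the mixture experiment. Abca4, Rdh8, Opn1sw, Opn1mw, Gfap, Edn2, Ccl2, Drd2, Adrb1 and Adra1a were always included. Some genes that the rule names are not reported here. Members that went against their list, and the genes behind counts of 5 or fewer, were chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry (limma 3.58.1), adjusted over the lists of each comparison, 629 tests in all. A count "adjusted over the list alone" corrects only over the members of that list.

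The light score averages the log2 CPM (prior count 1) of genes that changed at least 2-fold with light in the other experiment, as those raised minus those lowered. Groups were compared by two-sided exact permutation tests. The lens-fibre score was defined after lens transcripts were seen to vary, and its threshold is 4. Intervals of differences are at a confidence level of 95%.

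The tests were checked on simulated data: counts with 200 changed genes, drawn for each of the 17 comparisons. edgeR recovered 84.8 to 97.0% of 4-fold changes, 59.7 to 79.1% of 2-fold changes and 23.9 to 43.3% of 1.5-fold changes, and 1.67 to 6.38% of its calls were false. For limma voom 1.56 to 7.14% of calls were false, and for DESeq2 1.42.0 the share was 12.0 to 20.9%. Genes were drawn independently, with the spread that edgeR estimated. The simulated data therefore lack the variation that genes share between real libraries, such as that of lens transcripts.

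The alternatives were RLE size factors, no filter on low counts, DESeq2, limma voom, replicate number as a block, a fit of only the groups compared, the authors' FPKM values per transcript (limma on the log2 of FPKM plus a pseudocount of 1), and each library left out in turn. Those added after the data were examined were the lens-fibre score as a covariate, only libraries with a score under 4, and, for the light score, its alternatives, among them all genes called in the other experiment. For a named gene the FPKM result is that of its transcript with the highest mean FPKM. It can differ from the summed count of the gene, and other transcripts of the gene are not reported.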

Results

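RNA from the neural retina of Abca4-/-Rdh8-/- mice was sequenced in 30 libraries. These mice lack a transporter and a dehydrogenase that clear all-trans-retinal from photoreceptor outer segments, and bright light damages their photoreceptors. The mice were 4 to 6 weeks old and were housed in 12 h of light, of at most 10 lux, and 12 h of dark. No light means here that the bright exposure was not given. Illuminated animals received 10000 lux for 30 min, and the retina was taken 24 h later. Drug or the solvent DMSO was injected 30 min before the light. The mixture experiment (combined in the plots) had 4 groups of 3 libraries: no light with DMSO, light with DMSO, and light after BMT or MDB. BMT held bromocriptine (BRM), metoprolol (MTP) and tamsulosin (TAM), and MDB held metoprolol, doxazosin (DOX) and bromocriptine. The single-drug experiment (mono in the plots) had 6 groups of 3 libraries: no light, light, and light after BRM, MTP, TAM or DOX alone. No group of either experiment received drug without light. Bromocriptine is an agonist of D2-type dopamine receptors, metoprolol blocks the beta-1 adrenergic receptor, and tamsulosin and doxazosin block alpha-1 adrenergic receptors. Gene counts summed to 18.5 to 25.8 M per library in the mixture experiment and to 12.0 to 22.2 M in the single-drug experiment, with the lowest total in TAM replicate 1. Expression values are CPM, counts scaled to library size (TMM) per 1 M, as mean ± SD over 3 libraries. Log2 fold changes carry their SE, and their adjusted p comes from edgeR's quasi-likelihood test. The labels do not say whether each library came from a different animal, so these p-values measure the spread between libraries.

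Transcripts of both disrupted genes were counted in every group. Abca4 (ENSMUSG00000028125, chromosome 3, 122044443 to 122180061 in GRCm38.p3) stood at 662 ± 75.0 CPM without light and 405 ± 19.8 CPM after light in the mixture experiment, and at 762 ± 64.7 and 354 ± 29.7 CPM in the single-drug experiment. Rdh8 (ENSMUSG00000053773, chromosome 9, 20818504 to 20826163) stood at 40.0 ± 7.64 and 31.4 ± 1.54 CPM, and at 35.8 ± 3.82 and 23.1 ± 3.23 CPM. Whole-gene counts without wild-type retina cannot check a deletion of part of a gene, so these values do not test the genotype labels.

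Lens-fibre transcripts varied strongly between libraries of the same group. A lens-fibre score, the mean log2 CPM of 6 lens-fibre genes such as Mip, Lim2 and Bfsp2, ranged from -1.66 to 7.69 and was at least 4 in 16 of 30 libraries. Those were all 3 libraries of MDB, of BRM and of light in the single-drug experiment, and 1 library of each other group.

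The first comparison asks what bright light did to the retina in the absence of drug. In both experiments the lists of glial injury and interferon genes were higher and the rod and cone lists lower after light by camera at its preset correlation, and none of these list calls held with an estimated correlation (adjusted p from 0.0934 to 0.207). Of 16007 genes tested in the mixture experiment, 1241 were higher and 876 lower after light, 2117 in all. Prss56, which encodes a secreted serine protease (ENSMUSG00000036480, chromosome 1, 87183313 to 87188405), went from 3.17 ± 1.71 to 170 ± 45.5 CPM, a log2 fold change of 5.74 ± 0.52 (adjusted p = 4.45e-05). The acute-phase protease inhibitor Serpina3n rose by 5.74 ± 0.84 (adjusted p = 0.00092). Nlrc5, a transactivator of MHC class I genes, rose by 5.22 ± 0.61, and Tap1, the peptide transporter of antigen presentation, by 4.61 ± 0.38. Edn2, an endothelin made by stressed photoreceptors (ENSMUSG00000028635, chromosome 4, 120161206 to 120167360), went from 2.10 ± 0.76 to 40.2 ± 6.69 CPM, a log2 fold change of 4.26 ± 0.70 (adjusted p = 0.00187). The other largest rises were in Lad1 (5.06), Tnnt2 (5.02), Steap4 (4.47), Igtp (4.23) and Map3k8 (4.22). Glb1l3, a galactosidase-like gene, fell most, with a log2 fold change of -2.34 ± 0.24 (adjusted p = 0.000103). Glul, the glutamine synthetase of Müller glia, went from 1274 ± 188 to 348 ± 31.2 CPM, at -1.87 ± 0.13 (adjusted p = 1.2e-05). Opn1sw, the short-wavelength cone opsin, changed by -1.74 ± 0.23 and Hdc by -1.66 ± 0.25. Col9a1 (-1.86), Ppap2c (-1.66), Fam107a (-1.60), Spc25 (-1.60) and Meig1 (-1.55) were also among the 10 largest falls, and the Col9a1 call was lost with FPKM (adjusted p = 0.0554). The naming rule required all 3 libraries of one group to lie above all 3 of the other, so that trait of these genes is no evidence. Of all 16007 genes tested 30.3% were separated in this way, and chance gives 10%. Without no-light replicate 3 the count was 1343, and without light replicate 1 it was 1310.

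Most rod and cone genes were lower after light in the mixture experiment. Of 30 rod genes 27 were lower and 0 higher after light (29 lower adjusted over the list alone), with a median log2 fold change of -0.81 (camera adjusted p = 1.56e-24, and adjusted p = 0.155 with an estimated correlation). The rod transcription factors Nr2e3 and Nrl changed by -1.43 ± 0.13 and -1.26 ± 0.16, and the cone opsin Opn1mw by -0.81 ± 0.10. Of 17 cone genes 11 were lower and 2 higher (12 and 2 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.38e-06, and adjusted p = 0.155 with an estimated correlation). The exceptions were Gnb3, a transducin subunit, at 1.38 ± 0.10, and Pde6c, the cone phosphodiesterase, at 0.46. Genes of glycolysis and hypoxia had 6 members lower and 1 higher of 27 (9 and 1 adjusted over the list alone) and a median of -0.23 (camera adjusted p = 0.00305, and adjusted p = 0.469 with an estimated correlation). Hk2 was lower at -0.55 ± 0.12 and Hk1 higher at 0.76 ± 0.12.

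Several glial, immune and stress lists were higher after light at the preset correlation. Of 23 gliosis and injury genes 15 were higher and 0 lower (18 higher adjusted over the list alone), with a median of 2.46 (camera adjusted p = 4.21e-14, and adjusted p = 0.0934 with an estimated correlation). Gfap, the intermediate filament of reactive glia (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), went from 28.2 ± 13.8 to 303 ± 39.5 CPM, a log2 fold change of 3.42 ± 0.41 (adjusted p = 0.000251), and the iron-binding Lcn2 rose by 3.52 ± 0.34. Of 28 interferon-response genes 24 were higher and 0 lower (26 higher adjusted over the list alone), with a median of 2.45 (camera adjusted p = 3.44e-24, and adjusted p = 0.0934 with an estimated correlation). The transcription factor gene Irf1 rose by 3.22 ± 0.23. Of 20 genes of gp130 and JAK-STAT signalling 15 were higher (15 higher and 1 lower adjusted over the list alone), with a median of 2.53 (camera adjusted p = 5.23e-13, and adjusted p = 0.0934 with an estimated correlation). Socs3, a feedback inhibitor of this pathway, rose by 3.95 ± 0.38 and the shared receptor Il6st by 1.59 ± 0.13. Chemokines and cytokines had 12 of 17 members higher (12 adjusted over the list alone), at a median of 1.5 (camera adjusted p = 1.73e-08, and adjusted p = 0.0934 with an estimated correlation), with Vcam1 at 1.503 ± 0.22. The monocyte chemokine Ccl2 stood at 0.0165 ± 0.0285 CPM without light and 2.67 ± 1.21 CPM after light. Photoreceptor and Müller stress factors had 8 of 13 higher (9 adjusted over the list alone), at a median of 2.08 (camera adjusted p = 1.28e-08, and adjusted p = 0.0934 with an estimated correlation), with the endothelin receptor Ednrb at 2.42 ± 0.28. Immediate early and AP-1 genes had 16 of 25 higher (19 adjusted over the list alone), at a median of 1.21 (camera adjusted p = 5.85e-12, and adjusted p = 0.0934 with an estimated correlation), with Atf3 at 3.31 ± 0.29. Genes of cell death and p53 had 10 of 26 higher and 1 lower (13 and 1 adjusted over the list alone), at a median of 0.60 (camera adjusted p = 3.83e-06, and adjusted p = 0.0934 with an estimated correlation). The kinase gene Ripk1 rose by 1.87 ± 0.14.

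In the single-drug experiment, of 16249 genes tested 1846 were higher and 2049 lower after light, 3895 in all, and without light replicate 2 the count was 2550. All 3 light libraries and 1 of the 3 no-light libraries had a lens-fibre score of at least 4, and with that score as a covariate the count was 4093. Prss56 (6.50 ± 1.07), Serpina3n (5.51 ± 1.27), Steap4 (4.64 ± 0.83), Lad1 (4.48 ± 0.96), Map3k8 (4.45 ± 0.56), Tap1 (4.38 ± 0.56), A2m (4.23), Tnnt2 (4.12), the oncostatin M receptor Osmr (4.10) and Gadd45b (3.82) rose most. Glb1l3 (-3.59 ± 0.43), Hdc (-3.17 ± 0.41), Ccdc24 (-2.17), Fndc1 (-2.16), Ppap2c (-2.08), Opn1sw (-1.99 ± 0.25), Scn4a (-1.93), Ppargc1b (-1.85) and Nr2e3 (-1.82 ± 0.23) were among the 10 largest falls. Of 30 rod genes 29 were lower (29 adjusted over the list alone), with a median of -1.32 (camera adjusted p = 1.69e-25, and adjusted p = 0.207 with an estimated correlation). Of 17 cone genes 12 were lower and 2 higher (13 and 2 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 5.41e-07, and adjusted p = 0.207 with an estimated correlation). Gfap went from 24.1 ± 7.02 to 283 ± 18.9 CPM, at 3.55 ± 0.64 (adjusted p = 0.00107). Of 22 gliosis and injury genes 16 were higher (18 adjusted over the list alone), with a median of 2.31 (camera adjusted p = 2.36e-09, and adjusted p = 0.207 with an estimated correlation). The interferon-response list of 28 genes had 24 higher (25 adjusted over the list alone), with a median of 2.21 (camera adjusted p = 1.91e-20, and adjusted p = 0.0969 with an estimated correlation). Of 27 genes of glycolysis and hypoxia 12 were lower and 1 higher (12 and 1 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 9.33e-05, and adjusted p = 0.247 with an estimated correlation).

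The light effects of the experiments share no library. Of 15868 genes tested in both, 855 were higher and 695 lower after light in both experiments, against 142.9 and 113.0 for independent lists, and 0 genes went opposite ways. The fold changes of all 15868 genes correlated with r = 0.526 across genes. For the 4444 genes called in either experiment, a choice that favours large changes, r was 0.804. Genes are not independent replicates. A test of the difference between the light effects over 16645 genes called 0 genes with edgeR (2518 at an unadjusted p under 0.05), 11 with limma voom and 423 with DESeq2. Without light replicate 3 of the single-drug experiment edgeR called 126 genes, and without no-light replicate 2 of the mixture experiment it called 4, Kmt2a, Mast2, Plekha6 and Xlr3b, which are named here only after their values were seen.

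**Figure D1:**
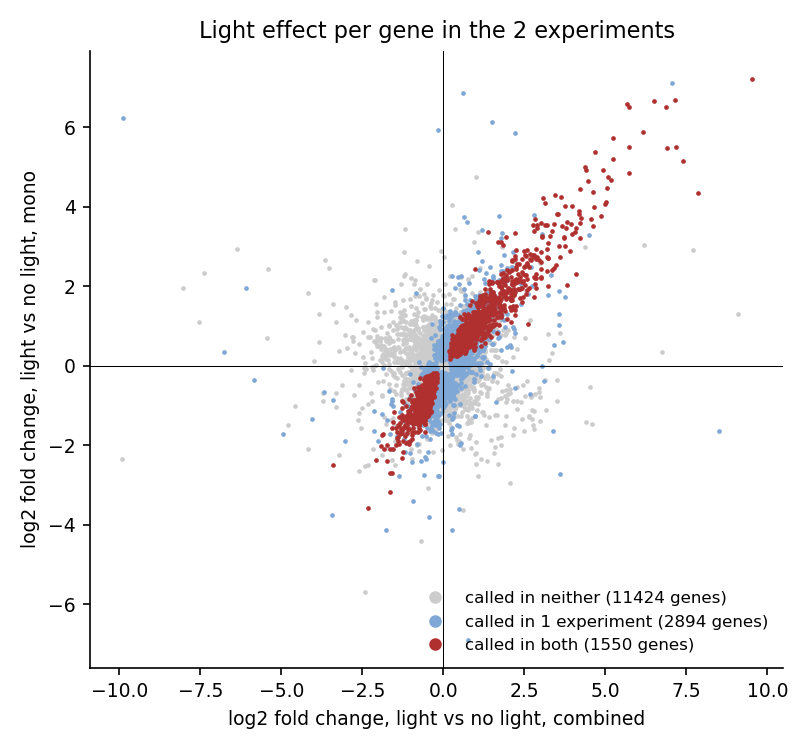
Log2 fold change of light versus no light for each gene in the mixture experiment (x axis) and the single-drug experiment (y axis), with genes called in both, in 1 or in neither marked by colour. The 1550 genes called in both changed in the same direction in both.

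The next comparison sets light after the 3-drug mixture BMT against light alone. Of 16007 genes tested 1274 were higher and 1566 lower with BMT before light than after light alone, 2840 in all. Glb1l3 rose most, at 2.88 ± 0.24 (adjusted p = 4.61e-05), and the 10 largest rises also held Fndc1 (2.37), Glul (1.85 ± 0.13), Opn1sw (1.75 ± 0.23), Fam107a (1.74), Hdc (1.74), Dleu7 (1.71), Papss2 (1.697) and Fam3c (1.57). The Papss2 call was lost with limma voom (adjusted p = 0.0527) and with FPKM (0.118, at 0.7681). Glul stood at 1255 ± 177 CPM after BMT, against 348 ± 31.2 after light and 1274 ± 188 without light. Prss56 fell most, at -6.02 ± 0.52 (adjusted p = 5.9e-05), and stood at 2.59 ± 1.82 CPM. Nlrc5 (-5.05 ± 0.59), Tap1 (-4.82 ± 0.38), the NF-kappaB cofactor Bcl3 (-4.38), Steap4 (-4.09), Irgm2 (-3.997), Junb (-3.82), Tnnt2 (-3.80), Serpina3n (-3.79) and Jak3 (-3.75) followed. Without light replicate 1, light replicate 2 or BMT replicate 3 the count was 1514, 1739 or 1519, and from the deposited FPKM values, tested per transcript, 1767 transcripts were called.

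With BMT, 29 of 30 rod genes were higher than after light alone (29 higher and 1 lower adjusted over the list alone), with a median of 0.81 (camera adjusted p = 5e-22, and adjusted p = 0.173 with an estimated correlation). Of 17 cone genes 11 were higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 3.86e-07, and adjusted p = 0.159 with an estimated correlation), and the lower ones were again Gnb3 and Pde6c. Of 28 interferon-response genes 21 were lower (25 adjusted over the list alone), with a median of -2.15 (camera adjusted p = 5.03e-20, and adjusted p = 0.155 with an estimated correlation). Of 23 gliosis and injury genes 14 were lower (16 adjusted over the list alone), with a median of -1.77 (camera adjusted p = 2.3e-10, and adjusted p = 0.159 with an estimated correlation). Gfap stood at 55.9 ± 26.4 CPM, at -2.44 ± 0.39 (adjusted p = 0.00175), and Stat3 at -2.08 ± 0.26. Immediate early and AP-1 genes had 18 of 25 members lower (20 adjusted over the list alone), at a median of -1.22 (camera adjusted p = 8.78e-12, and adjusted p = 0.155 with an estimated correlation). Of 13 mitochondrially encoded genes 7 were higher (11 adjusted over the list alone), at a median of 0.45 (camera adjusted p = 1.27e-05, and adjusted p = 0.509 with an estimated correlation), with mt-Cytb at 0.51 ± 0.13. With FPKM the calls of mt-Co3 (adjusted p = 0.164), mt-Cytb (0.213), mt-Nd5 (0.127) and mt-Nd4l (0.121) were lost. BMT replicate 3 had 9.07% of its counts in mitochondrial genes, the highest share of the 30 libraries, against 6.08 to 7.95% in the others.

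The same comparison for MDB gave 593 genes higher and 949 lower than after light alone, 1542 in all. The largest falls were in genes that light had raised: Prss56 (-6.22 ± 0.53, adjusted p = 4.62e-05), Serpina3n (-4.67 ± 0.79), Nlrc5 (-4.64 ± 0.58), Lad1 (-4.14), Tap1 (-3.95 ± 0.36), Steap4 (-3.85), Scube1 (-3.75), Socs3 (-3.65 ± 0.37), Usp18 (-3.55) and Igtp (-3.45). The largest rises were in Spon2 (4.25 ± 0.93, adjusted p = 0.0133), Ltbp2 (4.01), Islr (3.09), Col9a1 (2.82), Glb1l3 (2.77 ± 0.24), Col4a3 (2.67), Col4a4 (2.57), Sned1 (2.53), Crhbp (2.52) and Aldh1a7 (2.51). The Col4a3 call was lost with the replicate block (adjusted p = 0.0514), and the Col4a4 and Islr calls with FPKM (0.0515 and 0.0833). Spon2, Ltbp2, Sned1 and the collagen genes encode extracellular matrix proteins. All 3 MDB libraries had a lens-fibre score of at least 4, against 1 of the 3 light libraries. With that score as a covariate 1701 genes were called, 1228 of them among the 1542, and the median of the 10 largest rises went from 2.72 to 1.63. Without light replicate 1, light replicate 2 or MDB replicate 3 the count was 919, 993 or 982, and from the deposited FPKM values, tested per transcript, 1027 transcripts were called.

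With MDB, 23 of 30 rod genes were higher than after light (27 higher and 1 lower adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.24e-19, and adjusted p = 0.218 with an estimated correlation). Of 17 cone genes 10 were higher and 2 lower (12 and 3 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 7.7e-05, and adjusted p = 0.291 with an estimated correlation). The interferon-response list of 28 genes had 20 lower (23 adjusted over the list alone), with a median of -2.02 (camera adjusted p = 2.28e-22, and adjusted p = 0.132 with an estimated correlation). Of 23 gliosis and injury genes 12 were lower (13 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 2.89e-10, and adjusted p = 0.153 with an estimated correlation). Gfap stood at 41.1 ± 12.2 CPM, at -2.88 ± 0.40 (adjusted p = 0.000908). Crystallin and lens genes had 0 of 20 members called with edgeR (0 adjusted over the list alone) and a median of 2.67 (camera adjusted p = 2.93e-05, and adjusted p = 0.687 with an estimated correlation).

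**Figure D2:**
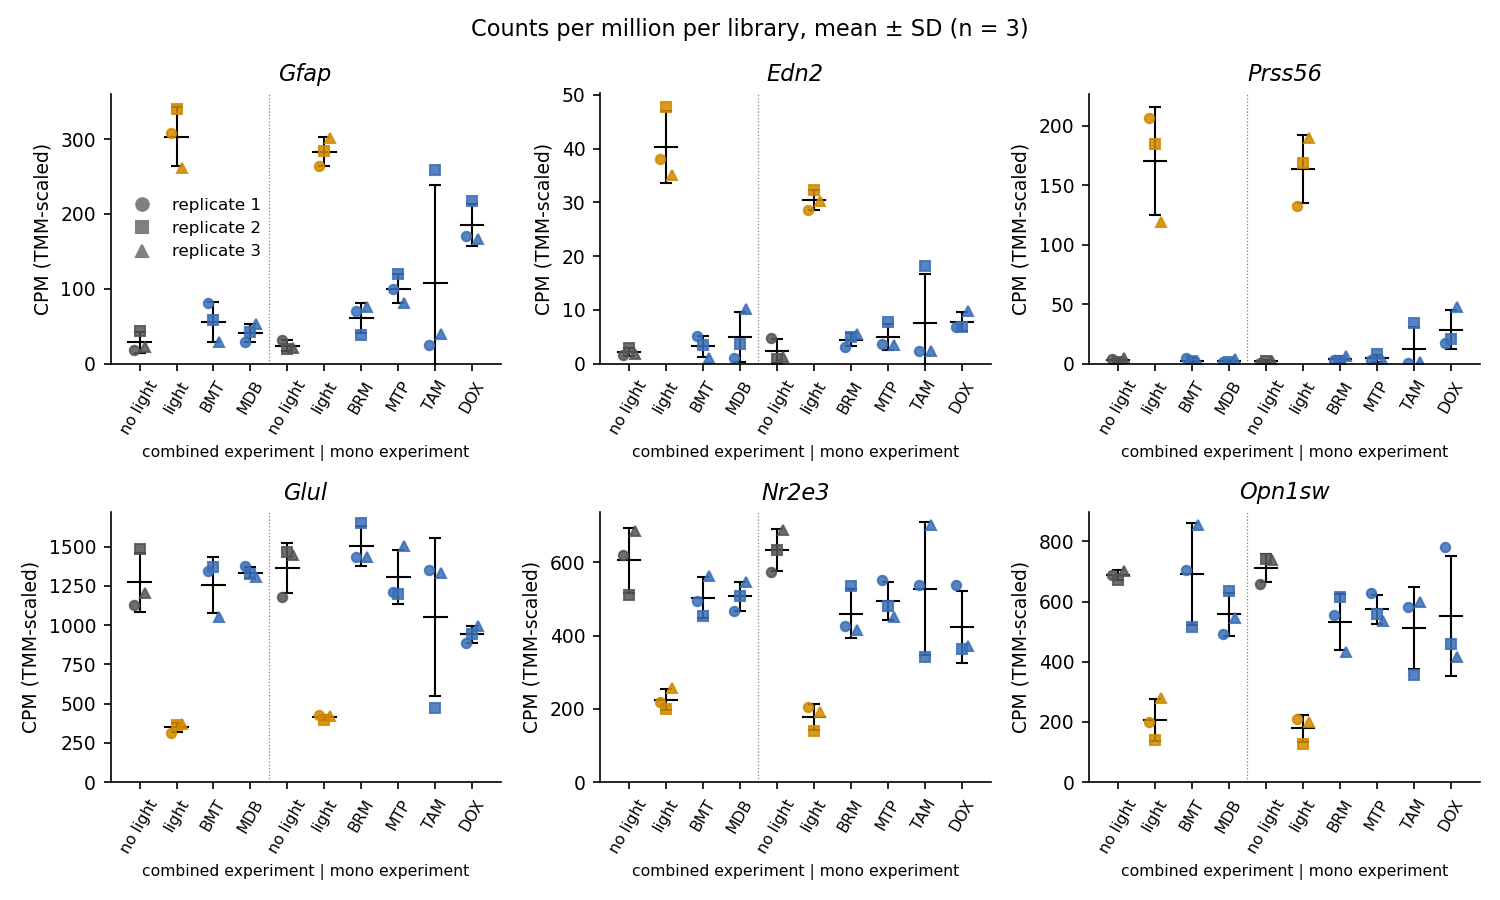
CPM of Gfap, Edn2, Prss56, Glul, Nr2e3 and Opn1sw in each of the 30 libraries (points) by group, with the group mean (line) and SD (bar), n = 3. Gfap stood at 303 CPM after light in the mixture experiment and at 55.9 and 41.1 CPM with BMT and MDB.

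The single-drug experiment asks what each compound did alone. With BRM 1151 genes were higher and 1190 lower than after light alone, 2341 in all. Glb1l3 (3.32 ± 0.43), Hdc (2.55), Fndc1 (2.13) and Glul (1.87 ± 0.27) were among the 5 largest rises, and Prss56 (-5.36 ± 0.99, adjusted p = 0.00363), Nlrc5 (-4.39 ± 0.72), Map3k8 (-4.21), Irgm2 (-4.03) and Serpina3n (-3.98) fell most. Of 30 rod genes 27 were higher and Samd7 lower (29 and 1 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 6.01e-20, and adjusted p = 0.246 with an estimated correlation). Of 28 interferon-response genes 24 were lower (26 adjusted over the list alone), with a median of -2.05 (camera adjusted p = 2.31e-25), a call that held with an estimated correlation (adjusted p = 0.0426). Of 22 gliosis and injury genes 11 were lower and Hspb1 higher (15 and 1 adjusted over the list alone), with a median of -1.51 (camera adjusted p = 1.96e-08, and adjusted p = 0.256 with an estimated correlation), and Gfap was lower at -2.20 ± 0.60 (adjusted p = 0.0244). All 3 BRM libraries and all 3 light libraries had a lens-fibre score of at least 4, but their ranges did not overlap. The score was 6.151 to 7.688 with BRM and 5.364 to 5.495 after light. With that score as a covariate the count of genes stayed within 1.5 times its main value. The count was 1254 without light replicate 1 and 910 without light replicate 2. It was 1498, 978 and 1336 without BRM replicate 1, 2 and 3.

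With MTP 873 genes were higher and 798 lower than after light, 1671 in all. Glb1l3 (3.35 ± 0.43), Hdc (2.42), Ccdc24 (1.71) and Fndc1 (1.69, a call lost with limma voom at 0.0617 and with FPKM at 0.1) were among the 5 largest rises, and Prss56 (-5.18 ± 0.99, adjusted p = 0.00432), Nlrc5 (-4.83 ± 0.74), Map3k8 (-4.45), Usp18 (-4.42) and Tap1 (-4.35) fell most. Of 30 rod genes 29 were higher (29 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 6.35e-30, and adjusted p = 0.152 with an estimated correlation). The interferon-response list of 28 genes had 24 lower (26 adjusted over the list alone), with a median of -1.92 (camera adjusted p = 6.35e-30), a call that held with an estimated correlation (adjusted p = 0.0228). Of 22 gliosis and injury genes 12 were lower (16 adjusted over the list alone), with a median of -1.57 (camera adjusted p = 1.55e-11, and adjusted p = 0.162 with an estimated correlation), and Gfap stood at 100.3 ± 19 CPM, at -1.50 ± 0.59 (adjusted p = 0.125). Extracellular matrix and wound genes had 7 of 23 lower (7 adjusted over the list alone), at a median of -0.94 (camera adjusted p = 4e-06, and adjusted p = 0.211 with an estimated correlation), with Spp1 at -1.07 ± 0.16. All 3 light libraries and 1 of the 3 MTP libraries had a lens-fibre score of at least 4. With that score as a covariate the count of genes was 1307, and the matrix and wound list was lower at a camera adjusted p of 0.000356. Crystallin and lens genes were lower with MTP at a median of -0.29 (0 of 20 called by edgeR, 0 adjusted over the list alone, camera adjusted p = 0.00546, and adjusted p = 0.568 with an estimated correlation), a direction that turned with the covariate (adjusted p = 0.958). The count of genes was 1097 and 801 without light replicate 1 and 2, and 882 and 1002 without MTP replicate 1 and 3.

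With TAM 1072 genes were higher and 650 lower than after light, 1722 in all. Glb1l3 (3.68 ± 0.44), Hdc (2.69), Fndc1 (1.94) and Ppap2c (1.72) were among the 5 largest rises, and Prss56 (-3.71 ± 0.91, adjusted p = 0.0161), Map3k8 (-3.50 ± 0.53), Irgm2 (-3.29), Igtp (-3.10) and Tap1 (-3.10) fell most. In a fit of only the groups compared the calls of Prss56 (adjusted p = 0.112), Fndc1 (0.0683) and Ppap2c (0.0517) were lost, and that of Fndc1 also with limma voom (0.0743) and FPKM (0.0615). Of 30 rod genes 29 were higher (29 adjusted over the list alone), with a median of 1.06 (camera adjusted p = 8.18e-32, and adjusted p = 0.204 with an estimated correlation). Of 28 interferon-response genes 22 were lower (25 adjusted over the list alone), with a median of -1.55 (camera adjusted p = 6.9e-26), a call that held with an estimated correlation (adjusted p = 0.0422). Of 22 gliosis and injury genes 7 were lower (10 adjusted over the list alone), with a median of -1.48 (camera adjusted p = 1.55e-09, and adjusted p = 0.204 with an estimated correlation). The TAM libraries differed widely: Gfap stood at 24.98, 258.5 and 39.01 CPM in replicates 1, 2 and 3, at -1.39 ± 0.58 relative to light (adjusted p = 0.150). The count was 840 without light replicate 2 and 597 without TAM replicate 3, and it was 298 when only the TAM and light libraries were fitted. All 3 light libraries and 1 of the 3 TAM libraries had a lens-fibre score of at least 4. With that score as a covariate the count stayed within 1.5 times its main value.

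With DOX 1104 genes were higher and 823 lower than after light, 1927 in all (1352 and 648 with RLE size factors). Glb1l3 (2.94 ± 0.43), Hdc (2.45), Fndc1 (1.73), Ccdc24 (1.72) and Ppap2c (1.68) rose most, and Map3k8 (-4.19 ± 0.55, adjusted p = 0.00106), Irgm2 (-3.45), Usp18 (-3.45), Nlrc5 (-3.41 ± 0.67) and Tap1 (-3.18) fell most. The Fndc1 call was lost with FPKM (adjusted p = 0.071). Of 30 rod genes 28 were higher (29 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 2.06e-25, and adjusted p = 0.279 with an estimated correlation). The interferon-response list of 28 genes had 21 lower (25 adjusted over the list alone), with a median of -1.41 (camera adjusted p = 6.62e-23, and adjusted p = 0.0662 with an estimated correlation). Of 22 gliosis and injury genes 4 were lower, namely Lcn2, Cp, C3 and A2m (7 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 9.62e-06, and adjusted p = 0.398 with an estimated correlation). The Cp call was lost with FPKM (0.0584) and the C3 call in a fit of only the groups compared (0.0755). Gfap stood at 185 ± 27.8 CPM, at -0.61 ± 0.57 relative to light (adjusted p = 0.521), and Stat3 at 137.5 ± 13.7 CPM. The count was 877 without light replicate 1, 492 without light replicate 2 and 443 without DOX replicate 1. It was 1065 when only the DOX and light libraries were fitted. All 3 light libraries and 1 of the 3 DOX libraries had a lens-fibre score of at least 4. With that score as a covariate the count stayed within 1.5 times its main value.

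**Figure D3:**
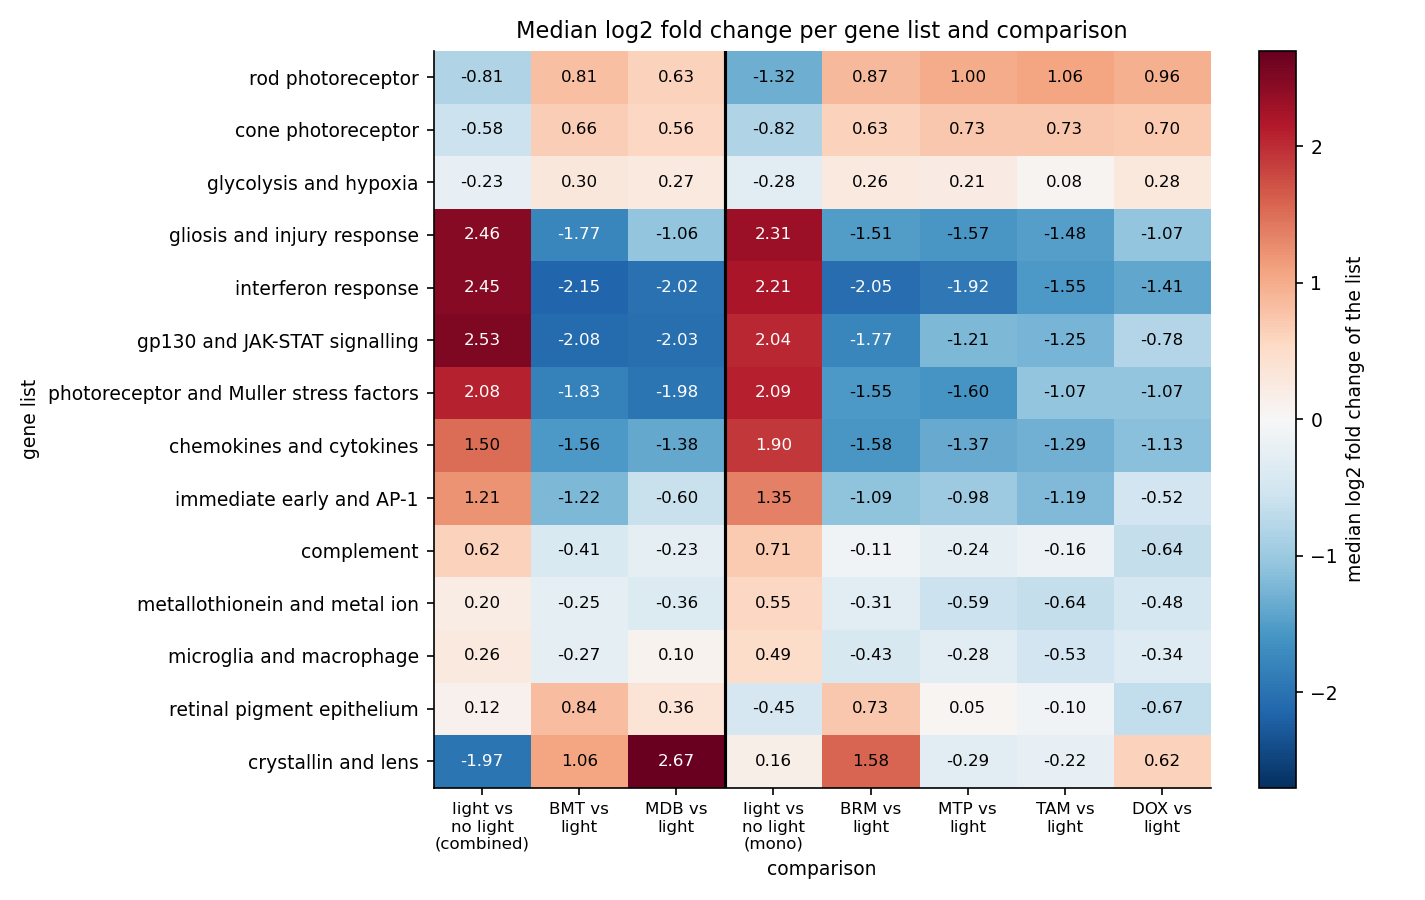
Median log2 fold change of 14 gene lists (rows) in light versus no light and in each treatment versus light (columns), with the colour scale in log2 units. The interferon-response list has a median of 2.45 for light in the mixture experiment and -2.15 and -2.02 for BMT and MDB versus light.

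Light-response genes taken from the other experiment were used to measure how far each treatment lay from light towards no light. In this way no library served both to choose the genes and to score the treatment. As no group received drug without light, a drug's own effect on these genes cannot be told apart from a change of the light response. Of the genes that light raised in the single-drug experiment, 806 were lower with BMT and 703 lower with MDB than after light, against 180.5 and 109.2 for independent lists. Of the genes that light lowered there, 806 and 435 were higher with BMT and MDB, against 164.3 and 76.5. Of the genes that light raised in the mixture experiment, 625 were lower with BRM, 534 with MTP, 434 with TAM and 368 with DOX, against 92.15, 61.69, 50.4 and 63.79. Of those that light lowered, 447, 543, 583 and 458 were higher, against 63.49, 48.14, 59.18 and 60.95. All 12 sets moved against the light effect by camera, and all 12 also with an estimated correlation (highest adjusted p = 0.0438). A light score over genes that changed at least 2-fold in the other experiment was scaled to 0 in the no-light mean and 1 in the light mean. It was 0.0898 ± 0.165 (SD, n = 3) with BMT and 0.145 ± 0.00929 with MDB, and 0.195 ± 0.106 with BRM, 0.172 ± 0.0870 with MTP, 0.232 ± 0.354 with TAM and 0.377 ± 0.0735 with DOX. The mixtures were scored on 598 raised and 341 lowered genes, and the single drugs on 554 and 101. Each experiment was scaled to its own controls, so these scores do not rank mixtures against single drugs. Without TAM replicate 2 the TAM mean was 0.0277, and without BMT replicate 2 or 3 the BMT mean was 0.0213 or 0.179. All 3 libraries of each treatment scored below all 3 light libraries. A two-sided exact permutation test of 3 against 3 cannot go below p = 0.1, the value each treatment gave against light (0.15 adjusted over 21 comparisons). The 4 single drugs together gave an exact permutation p of 0.590 over 15400 partitions, a test in which the spread of the TAM libraries enters. In pairs, all 3 BRM and all 3 MTP libraries scored below all 3 DOX libraries (differences of -0.182 and -0.205, exact p = 0.1, the smallest possible, and 0.15 adjusted for each).

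**Figure D4:**
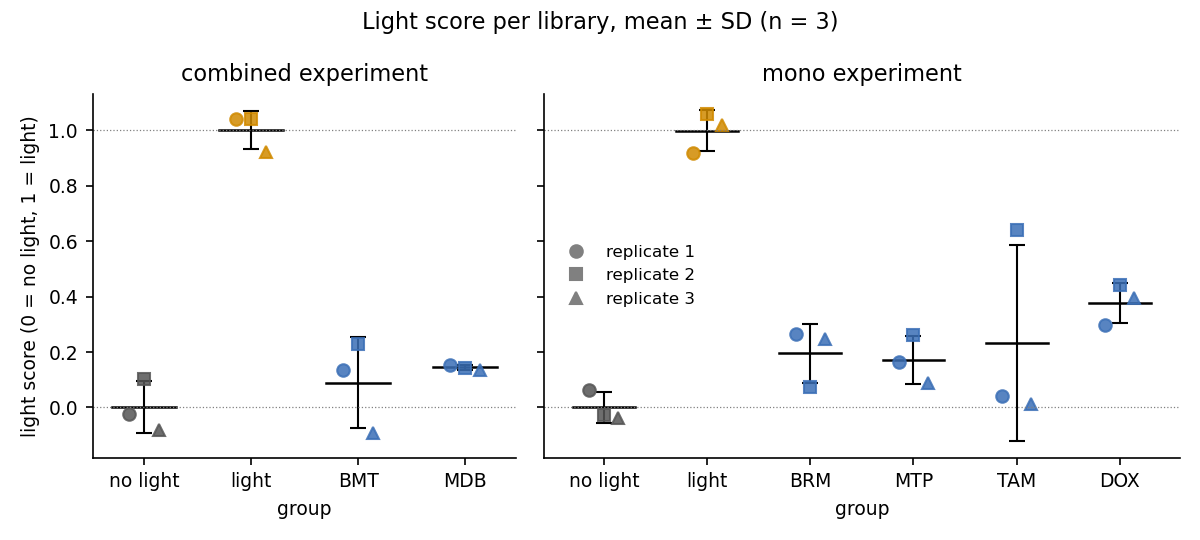
Light score of each library (points), on a scale where the no-light mean is 0 and the light mean is 1, by group, with group mean (line) and SD (bar), n = 3. DOX libraries lie between 0.296 and 0.440 and TAM libraries between 0.0136 and 0.640. Each experiment has its own genes and its own scale, so scores are not comparable between the experiments.

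Each treatment was also compared with the no-light group of its experiment. A difference can be a remainder of the light response or an effect of the drug itself, which this design cannot separate. The genes that light raised in the other experiment were higher than without light in each treatment by camera, at medians of 0.06 for BMT (adjusted p = 6.76e-06), 0.05 for MDB (0.0468), 0.17 for BRM (7.49e-07), 0.15 for MTP (3.06e-09), 0.20 for TAM (5.55e-18) and 0.29 for DOX (2.43e-31). The MDB call was lost with RLE size factors (0.0501), without a filter on low counts (0.071) and with the lens covariate (0.316, at a median of 0.024), and it held for the genes that changed at least 2-fold (6.37e-10). None of these sets, nor those that light lowered, was called with an estimated correlation (lowest adjusted p = 0.254) or with fry (lowest adjusted p = 0.0712). The light scores of MDB, BRM, MTP and DOX lay above those without light at the smallest p that 3 against 3 allows (two-sided exact permutation p = 0.1, 0.15 adjusted). For BMT and TAM that exact p was 0.5 and 0.3. The light score was not adjusted for the lens-fibre score. All 3 MDB and all 3 BRM libraries were lens-rich, against 1 of the 3 no-light libraries of each experiment. In each group with 1 lens-rich library, except TAM and light of the mixture experiment, that library had the highest light score. A part of lens content in the MDB and BRM scores therefore stays open. Gene by gene, edgeR called 0 genes for each of the 6 treatments. The libraries did not overlap with those without light for 9.18% of genes with BMT, 14.6% with MDB and 25.3% with BRM. The share was 15.9% with MTP, 11.2% with TAM and 17.7% with DOX, where chance gives 10%. At an unadjusted p under 0.05 there were 1009 genes for BMT, 1642 for MDB, 2535 for BRM, 1395 for MTP, 1327 for TAM and 2110 for DOX. With 1 library left out this count ranged from 558 to 2103 for BMT and from 934 to 3641 for MDB. With the lens covariate it was 933 for MDB, so these counts do not rank the treatments. DESeq2 called 13 genes for BMT, 23 for MDB, 414 for BRM, 3 for MTP, 7 for TAM and 40 for DOX. The 3 for MTP were 6330403K07Rik, Egln1 and Hace1, named only after their values were seen. Limma voom called 1 gene, Wisp1, for BRM at -1.03 (adjusted p = 0.0412), likewise named afterwards, and 0 for the other treatments. Leaving out no-light replicate 2 gave 1 gene for BMT, Gm9752. Leaving out TAM replicate 1 or 2 gave 1 gene for TAM, Gm9008 or Tmem254c, also named afterwards. Fitting only the DOX and no-light libraries gave 34 genes for DOX. With DOX 0 of 22 gliosis and injury genes were called over all genes and 13 were higher adjusted over the list alone, with a median of 1.54 (camera adjusted p = 1.55e-11, and adjusted p = 0.271 with an estimated correlation). Gfap was at 2.94 ± 0.63 (adjusted p = 0.283). Of 20 gp130 and JAK-STAT genes 0 were called and 11 were higher adjusted over the list alone, with a median of 1.14 (camera adjusted p = 5.68e-09, and adjusted p = 0.271 with an estimated correlation). With TAM 8 gliosis and injury genes were higher adjusted over the list alone, at a median of 1.30 (camera adjusted p = 2.12e-06, and adjusted p = 0.633 with an estimated correlation). With BRM 0 of 30 rod genes were called and 20 were lower adjusted over the list alone, with a median of -0.46 (camera adjusted p = 1.01e-14, and adjusted p = 0.464 with an estimated correlation). All 3 BRM libraries and 1 of the 3 no-light libraries were lens-rich, and the crystallin and lens list was higher in this comparison at a median of 1.64 (0 of 20 called by edgeR, 0 adjusted over the list alone, camera adjusted p = 0.00048, and adjusted p = 0.621 with an estimated correlation). With the lens-fibre score as a covariate the rod photoreceptor list had a median of -0.39 (camera adjusted p = 5.85e-13).

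Tamsulosin, a sulfonamide phenethylamine, and doxazosin, a quinazoline, both block alpha-1 receptors, so their libraries compare different structures with a shared target. The doses are not given in the sources used here. Between TAM and DOX edgeR called 0 of 16249 genes (2519 at an unadjusted p under 0.05), limma voom 0 and DESeq2 130. The libraries of the 2 groups did not overlap for 16.7% of genes, where chance gives 10%. The 0 calls therefore do not show that the drugs are alike. The 95% interval of the log2 difference had a median half-width of 0.34 over all genes and was wider for several genes of the light response. Gfap differed by -0.78 (95% interval -2.01 to 0.46, adjusted p = 0.551), Edn2 by -0.0086 (-1.44 to 1.42), Prss56 by -1.19 (-2.98 to 0.611) and Serpina3n by -0.388 (-2.61 to 1.83), so large differences in these genes stay open. The light score differed by -0.145 (two-sided exact permutation p = 0.4, 0.525 adjusted over 21 comparisons). This rests on TAM replicate 2, at 0.640: without it the TAM mean was 0.0277 against 0.377 for DOX, and the other TAM libraries, at 0.042 and 0.0136, lay below all 3 DOX libraries (0.296 to 0.440). Without TAM replicate 2 edgeR called 48 genes. Without TAM replicate 1 it called 3, Bst1, Gm9008 and Gm14440, and without DOX replicate 3 it called 1, Gm6472, named after their values were seen.

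By their labels BMT and MDB share bromocriptine and metoprolol and differ in holding tamsulosin or doxazosin. Whether the shared drugs had equal doses is not given in the sources used here. Between BMT and MDB edgeR called 0 of 16007 genes (3001 at an unadjusted p under 0.05), limma voom 0 and DESeq2 716. The libraries of the 2 groups did not overlap for 27% of genes, where chance gives 10%. The 0 calls therefore do not show that the mixtures are alike. With the lens-fibre score as a covariate edgeR again called 0, and 1323 genes had an unadjusted p under 0.05. The median half-width of the 95% interval was 0.31. Opn1mw, the middle-wavelength cone opsin, differed by 0.43 (95% interval 0.20 to 0.66, adjusted p = 0.185), Gfap by 0.45 (-0.39 to 1.28), Prss56 by 0.199 (-1.02 to 1.42) and Serpina3n by 0.877 (-0.701 to 2.46). The light score differed by -0.0549 (two-sided exact permutation p = 0.7, 0.817 adjusted over 21 comparisons), and its direction rests on 1 library: the BMT mean was 0.179 without BMT replicate 3 and 0.0213 without BMT replicate 2, against 0.145 for MDB. Crystallin and lens genes were lower with BMT at a median of -1.65 (0 of 20 called by edgeR, 0 adjusted over the list alone, camera adjusted p = 9.2e-05, and adjusted p = 0.822 with an estimated correlation), as was the lens-fibre score, which was at least 4 in 1 BMT library and 3 MDB libraries.

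The deposited tables of changed transcripts list 521 transcripts of 474 genes for the mixture experiment and 622 transcripts of 567 genes for the single-drug experiment. Of those genes 442 and 525 were called here in at least 1 comparison with light. The deposited log2 fold change is that of no light against light, so its sign was turned before it was compared with the light effect fitted here. The direction was then the same for 506 of 521 and 607 of 622 transcripts, with r = 0.908 and 0.930 across transcripts.

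**Figure D5:**
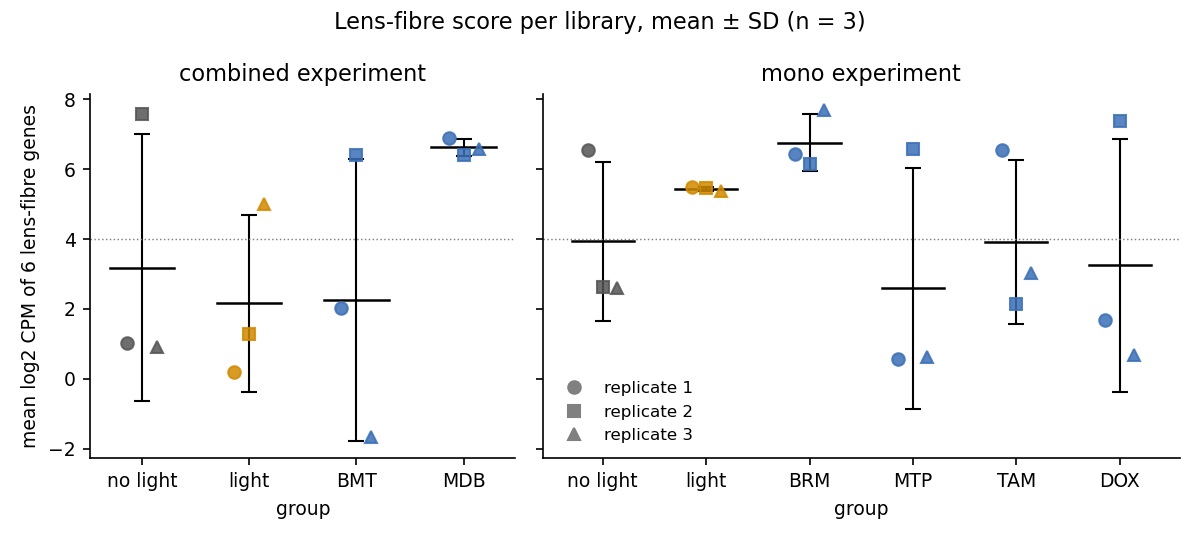
Lens-fibre score, the mean log2 CPM of 6 lens-fibre genes, of each of the 30 libraries (points) by group, with a line at the threshold of 4. All 3 libraries of MDB, BRM and light in the single-drug experiment lie above the line.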

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

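The tests of the drug as a source of lens transcripts, of the lens-rich no-light libraries, of the genes still called with the covariate, and of TAM replicate 2 were chosen after the result was seen. The lens-fibre gene ratios and the covariate's effect on the MDB genes were tested with bounds written before their results were seen.

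Lens-fibre transcripts varied strongly between libraries of 1 group, with a lens-fibre score from -1.66 to 7.69 over all libraries. Of the 12 libraries without drug 6 had a lens-fibre score of at least 4, which argues against the drug as their only source. It cannot exclude a part of the drug in MDB and BRM, where all 3 libraries reached that score. Lens tissue carried along at dissection could explain them, and would hold the 6 lens-fibre genes at 1 ratio. Over the 16 lens-rich libraries the largest SD of a gene's log2 ratio to the other 5 was 0.619, which lies between the bounds set for and against. Carried lens tissue therefore stays open, and no biological explanation other than the drug was tested.

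The 10 genes with the largest rises in MDB versus light, among them Spon2, Ltbp2 and Col4a3, may in part come from lens-side tissue, as all 3 MDB libraries had a high lens-fibre score (6.409 to 6.884). With the lens-fibre score as a covariate their median log2 fold change went from 2.72 to 1.63, 59.9% of its value, just under the 60 percent bound set for this explanation. In both experiments 9 of the 10, all but Glb1l3, were highest in the lens-rich no-light library, which had neither drug nor bright light. All 10 of the 10 stayed called with the covariate, which argues against a part linear in that score as the whole cause. An effect of MDB on these genes, in retina or in adjoining tissue, stays open.

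TAM replicate 2 kept more of the light response than the other TAM libraries. Its light score of 0.640 lay below the lowest light library (0.917) by more than the SD of those libraries (0.0738), which argues against an undrugged light library under a TAM label. Its lens-fibre score of 2.14 was the lowest of the TAM libraries (highest 6.56), which argues against lens-side tissue. A smaller drug effect in that retina, such as a lower uptake of the injected drug, and a mixed sample stay open and were not tested.

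In 8 gene lists the light effect differed between the experiments by a test of the difference (single-drug minus mixture, camera at the preset correlation). The rod list differed by a median of -0.44 (adjusted p = 1.33e-09), the cone list by -0.31 (0.0103), the bipolar cell list by -0.22 (0.0299) and the synapse list by -0.30 (0.0476). The glycolysis and hypoxia list differed by -0.098 (0.0476), the cholesterol synthesis list by 0.23 (0.00099), the amacrine and horizontal cell list by 0.21 (0.0299) and the list of cAMP, G protein and phospholipase C signalling by 0.14 (0.0476). With an estimated correlation the adjusted p was 0.902 for each of the 8, and with fry it ranged from 0.462 to 0.805. The experiment is confounded with every difference between the occasions, and no explanation was tested.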

How the results depend on the processing

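The lens-fibre score as a covariate, the use of libraries with a score under 4 and all alternatives of the light score were chosen after the data were examined. RLE size factors and the replicate number as a block kept every count of genes within 1.5 times its main value. With the block the counts were 2014 and 3650 for light in the mixture and single-drug experiment, 2647 for BMT, 1566 for MDB, 2132 for BRM, 1563 for MTP, 1591 for TAM and 1584 for DOX versus light. On average libraries of equal number did not resemble each other (mean r of residuals across genes -0.0111 and -0.00885). For unequal numbers the means were 0.00957 and 0.00888. Single pairs of equal number ranged from -0.31 to 0.751 and from -0.465 to 0.657. The means show no pairing by number, and a weaker one under the spread of lens transcripts stays open.

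DESeq2, which made more false calls on simulated data, gave 13 genes for BMT, 23 for MDB, 414 for BRM, 3 for MTP, 7 for TAM and 40 for DOX versus no light. It gave 716 for BMT versus MDB, 130 for TAM versus DOX and 423 for the difference between the light effects, each 0 with edgeR. How many of these calls are false cannot be told from the simulated data, in which genes varied independently. limma voom gave 11 for that difference and 1 (Wisp1) for BRM versus no light, which was also the 1 gene without a filter on low counts. A fit of only the groups compared gave 298 genes for TAM and 1065 for DOX versus light, and 34 for DOX versus no light. Fewer libraries then estimate the spread.

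From the authors' FPKM, 17982 and 18483 transcripts were tested in place of genes, so the counts differ in kind, and the cause of a difference was not tested. BMT versus light gave 1767 transcripts and MDB versus light 1027. MDB versus no light gave 3 (Rtn4, Scamp1, Stard10), BMT versus MDB 2 (Scamp1, Hnrnpl), TAM versus DOX 3 (Lrpap1, Rbfox2, Ndufc1), and BRM, MTP and TAM versus no light 1 each (Phldb1, Impg1, Ndufc1). These genes were named after their values were seen. Dhcr7 in BMT versus light changed sign to -1.02 (adjusted p = 0.415) in its transcript with the highest mean FPKM. The cause was not tested. Among libraries with a lens-fibre score under 4, MTP versus no light gave 19 genes, and the cause was not tested.

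Leaving out 1 library gave 1310 to 2781 genes for light in the mixture experiment and 2550 to 3605 in the single-drug experiment. Versus light the ranges were 1514 to 2589 for BMT, 919 to 1376 for MDB, 910 to 2491 for BRM, 801 to 1313 for MTP, 597 to 2446 for TAM and 443 to 2283 for DOX. Versus no light they were 0 to 1 for BMT and TAM, and 0 to 0 for MDB, BRM, MTP and DOX. They were 0 to 0 for BMT versus MDB, 0 to 48 for TAM versus DOX and 0 to 126 for the difference between the light effects. The libraries whose loss lowered a count the most were no-light replicate 3 (1343) and light replicate 1 (1310) for light in the mixture experiment, light replicate 2 (2550) for light in the single-drug experiment, light replicate 1 (1514) for BMT and light replicate 1 (919) for MDB. For the single drugs they were light replicate 2 for BRM (910) and MTP (801), TAM replicate 3 (597) and DOX replicate 1 (443). TAM replicate 2 (48 without it) and light replicate 3 of the single-drug experiment (126 without it) moved the counts of 0. The other libraries that moved a count by over 1.5 times are given with each comparison above. A group left with 2 libraries is assumed to vary like the others.

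Of 629 list tests 258 were called by camera at the preset correlation, 3 with an estimated correlation and 139 with fry, 122 of them among the 258. The 3 are the interferon-response list for BRM, MTP and TAM versus light. Nearly all list calls at the preset correlation were therefore lost with an estimated correlation. With fry, which uses no preset correlation, 122 of the 258 were kept. All lists called by fry were in light versus no light or in treatments versus light, with 0 in each other comparison. The light score kept each treatment below light under the alternatives run. Its largest shift was that of TAM, from 0.232 to 0.0277 without TAM replicate 2. The 12 light-response sets versus light were called under every setting run. With the lens-fibre score as a covariate the crystallin and lens list changed direction, as its genes define the score: adjusted p = 0.417 for MDB and 0.958 for MTP versus light, 0.177 for MDB and 0.420 for BRM versus no light, and 0.366 for BMT versus MDB. Of 758 calls of named genes, 6 were lost with RLE, 29 without the filter, 8 with voom, 25 with the block, 83 with only the groups compared and 24 with the covariate. DESeq2 lost 0 of 751. Of 716 calls FPKM lost 80 with their direction kept and 1 more, Dhcr7 above, with it turned. Depth and replicates limit small changes: on simulated data edgeR recovered 23.9 to 43.3% of 1.5-fold changes.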

Other observations

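The tests of the rod transcripts were chosen after the result was seen, and the splits of the libraries were planned. Light also moved genes outside the groups described above. Mt1 and Mt2, which encode metal-binding metallothioneins, rose by 2.24 ± 0.20 and 3.02 ± 0.29 on the log2 scale in the mixture experiment, and Axl, a receptor of phagocytosis, by 2.12 ± 0.22. P2ry12, a receptor of resting microglia, changed by -1.57 ± 0.22 in the mixture experiment and -2.10 ± 0.35 in the single-drug experiment. Cd68, a lysosomal protein of microglia and macrophages, changed by 2.19 ± 0.31 and 1.92 ± 0.49. P2ry12 was higher with each of the 6 treatments than after light in edgeR. The TAM call was lost with limma voom (adjusted p = 0.119) and in a fit of only the groups compared (0.16), and the DOX call in the latter (0.0767). The microglia and macrophage list as a whole had 3 of 23 genes higher and 1 lower in the mixture experiment (4 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.177).

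Of the receptors the drugs act on, Adrb1, the beta-1 receptor that metoprolol blocks, was lower after light at -0.65 ± 0.13 (adjusted p = 0.00657) in the mixture experiment and -0.80 ± 0.15 (adjusted p = 0.00159) in the single-drug experiment. It was higher than after light with BMT (0.53), MDB (0.67), BRM (0.57), MTP (0.62) and DOX (0.52), and with TAM the difference was 0.45 (adjusted p = 0.0731). The DOX call was lost with the replicate block (0.0548), only the groups compared (0.118), FPKM (0.08) and the lens covariate (0.068), the MTP call with that covariate (0.0532) and the BMT call with FPKM (0.0518). Drd2, the main receptor of bromocriptine, was not called after light in either experiment (adjusted p = 0.873 and 0.281). Adra1a, an alpha-1 receptor that tamsulosin blocks, stood at 1.79 ± 0.53 CPM after light and 0.538 ± 0.332 CPM with TAM in the single-drug experiment. It was lower with TAM than after light, at -1.68 ± 0.50 (adjusted p = 0.0446), and was not called after light (adjusted p = 0.113 and 0.563). The TAM call was lost without a filter on low counts (0.0555), with limma voom (0.0582), the replicate block (0.0712), only the groups compared (0.119) and the lens covariate (0.0702).

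Rod transcripts fell by different amounts, more than loss of a common share of rod RNA allows if all 30 genes are expressed in rods alone. The variance of the log2 fold changes over the 30 rod genes was 5.77 times their mean squared SE in the mixture experiment and 4.47 times in the single-drug experiment. A single common loss predicts a ratio near 1 in that case. Whether other retinal cells also express some of these genes was not tested, so a common loss of rod RNA stays open. The changes correlated with r = 0.812 across the genes, which are not independent replicates.

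Xist was counted at 1317 to 2499 CPM in all 30 libraries, and the Y-linked Ddx3y and Eif2s3y at 0 counts in all 30. The Y-linked Kdm5d had 18.7 to 106 counts in each library, and Uty 0 to 43.3. Transcripts of all these genes are listed in the deposited count tables. Whether the Kdm5d and Uty counts come from reads shared with their X-linked paralogs was not tested. The design text names male and female mice.

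The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real split, 1 of 10, gave 2117 genes for light in the mixture experiment (highest other 0), 2840 for BMT (0), 1542 for MDB (2), 3895 for light in the single-drug experiment (0), 2341 for BRM (0), 1671 for MTP (2), 1722 for TAM (0) and 1927 for DOX (1). Where edgeR called 0 genes, all 10 of 10 splits gave as many, which a real count of 0 fixes in advance. The highest other was 38 for BMT versus no light, 1 for BRM versus no light and 136 for TAM versus DOX. It was 0 for MDB, MTP, TAM and DOX versus no light and for BMT versus MDB. The 0 calls were from edgeR. The unadjusted counts and those of limma voom and DESeq2 stand with each comparison above. The split with 38 and the split with 136 point to a structure of the samples. The first put no-light replicates 1 and 3 with BMT replicate 3, the 3 libraries with the lowest lens-fibre scores (1.026, 0.913 and -1.661, against 7.58, 2.016 and 6.399). The second put TAM replicates 1 and 3 with DOX replicate 1, the 3 with the lowest light scores (0.042, 0.0136 and 0.296, against 0.640, 0.440 and 0.394). For the difference between the light effects all 100 of 100 drawn splits gave as many as the real 0, again fixed in advance. The highest gave 801, which also points to a structure of the samples.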
